A study of Mus musculus with 4 samples.

How the data were processed

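RNA of mouse testis was measured on 4 arrays of the Affymetrix Mouse Genome U74A version 2 design, 2 of Tslc1+/+ and 2 of Tslc1-/- mice, 16 weeks old. Per the labels' series design text, the authors reverse-transcribed 3 micrograms of RNA from an oligo(dT) primer carrying a T7 promoter, amplified it into biotin-labelled cRNA by in vitro transcription and hybridised the fragmented cRNA. The deposited values are probe set intensity on a linear scale: per the same text, the authors computed signals with Affymetrix Microarray Suite 5.0 (MAS5, also named in the submitters' processing notes) and scaled each array globally to a target of 1000. The values were checked against that statement: the mean after trimming 2% from each end was 1001 on each array, and values ran from 1.5 to 146239. Such scaling sets the arrays' overall brightness equal, so a change in total RNA per testis cannot be seen, and a fall of many bright transcripts is measured relative to the rest. Detection calls and probe-level data were not used here. The labels' reverse transcription from the poly(A) tail favours the 3' ends of transcripts.

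Samples were grouped by genotype as the titles give it. The number of arrays, 2 per genotype, limits the precision; a permutation test of 2 against 2 cannot give a two-sided p under 0.333. The groups, tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except where the text says otherwise. All 4 per-sample columns were used.

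Probe sets were named from the platform annotation, with symbols checked through Entrez identifiers against RefSeq genes of assembly GRCm38.p6, which was used for names, chromosomes and neighbourhood only, since no build is given in the sources used here. Of 12488 probe sets, 66 controls were left out of tests. Of the other 12422, 1 gene was listed for 10833, several for 396 and none for 1193, and no gene is named from a probe set with several; 10817 matched by Entrez identifier. Signals were used as log2(signal + 50) with no further normalization, over probe sets with a mean signal over the 4 arrays of at least 200. This left 7975 probe sets, 7170 with 1 gene, 278 with several and 527 with none, for 5992 distinct genes. Among them 1621 carried a suffix that marks possible cross-hybridisation. They include called probe sets of Cadm1, Pla2g12a, Arcn1, Ly6e, Actg2, Gapdhs, Tnp1, Tcp11, Akap1, Pkm and Aldoa. Genes are represented by their brightest probe set. Among tested probe sets of genes in the text, another one had the opposite sign for Abca1, Dazl and Ly6e, and below the signal filter this was so for Pla2g12a, Arcn1, Bub1 and Bcl2l1 among the genes named by the rule given here.

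The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), Tslc1-/- minus Tslc1+/+, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The trend was used because the spread falls with signal: the median SD of log2 values within a genotype was 0.43 from a signal of 200 to 500 and 0.08 above 10000. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 21 lists with at least 3 tested genes. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. None of the 3 called lists held with the estimated correlation. Cadm1 was in no list. Values are means ± SD over 2 arrays.

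The fits were tested on simulated data for the Tslc1-/- against Tslc1+/+ comparison, in 20 simulations of 7975 probe sets with 200 changed. With the trend, limma recovered 6.70% of changes of log2 size 0.5, 34.9% of size 1, 72.7% of size 2 and 97.5% of size 4, and 5.95% of its calls were false. For size 1 it recovered 98.2% above a signal of 5000 and 28.3% below. Without the trend it recovered 0%, 0.2%, 29.3% and 82.1%. The simulated spread was drawn from the trended fit. The simulation therefore favours the trend and does not give the share of false calls on the real arrays. For the fixed gene lists, a simulated list of 13 genes lowered by 0.45 was called in 100% of simulations with the preset correlation and in 0% with the estimated one, and lists left unchanged were called in 0%. The simulated probe sets varied independently, and the unchanged lists were drawn from probe sets of any signal. The 0% therefore does not check the preset correlation for bright genes that vary together.

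Genes were named by a fixed rule: Cadm1, the 5 genes with the largest rise and the 5 with the largest fall among called genes whose genotypes did not overlap, and from each list the member with the smallest p. From the spermatogonial, meiotic, round and elongating spermatid, Sertoli and Leydig lists the brightest member was added. Other list members named in the text, Ghitm, and the genes of the closing section outside this rule were chosen after their values were seen.

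The alternatives were pseudocounts of 1 and 200, no signal filter, a minimum mean signal of 500, quantile normalization, equal array medians, no intensity trend, the replicate number as a block, leaving out each array in turn, 1 probe set per gene, probe sets with no cross-hybridisation suffix, and the mean over a gene's probe sets. The flagellum list without the genes it shares with the elongating spermatid list was added after the data were seen. With 1 array left out, the lone array of its genotype is assumed to vary like the other genotype's arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.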

Results

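Messenger RNA of the mouse testis was measured on 4 Affymetrix arrays, 2 from Tslc1+/+ males and 2 from Tslc1-/- males, all 16 weeks old and of the C57BL/6J strain. Tslc1, named Cadm1 in current annotation, encodes a cell adhesion molecule of the immunoglobulin superfamily. Each array held 12488 probe sets, and the median signal per array was 361.5 and 378 in Tslc1+/+ and 377.7 and 365.15 in Tslc1-/-. Log2 signals of arrays of the same genotype correlated across probe sets with r = 0.934 (Tslc1+/+) and r = 0.938 (Tslc1-/-), and arrays of different genotype with r between 0.923 and 0.936. Probe sets are not independent replicates. At most 0.0961% of probe sets had identical values on any pair of arrays, so no array was a copy of another. Changes are given as log2 of Tslc1-/- over Tslc1+/+ after adding 50 to each signal, which understates changes of dim probe sets. The labels do not say that the arrays of a genotype came from separate animals, so the p-values measure only the spread between these arrays, which may be technical.

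The first comparison asked whether the targeted transcript differed between the genotypes. The Cadm1 signal fell in Tslc1-/- testis on both of its tested probe sets. On the first it went from 3943 ± 24.6 to 444.2 ± 0.990 (SD, n = 2), an 8.08-fold decrease and a log2 change of -3.01 with a standard error of 0.18 (limma, Benjamini-Hochberg adjusted p = 2.31e-05). On the second it went from 3739 ± 409 to 690.2 ± 121 (SD, n = 2), a 5.14-fold decrease and a log2 change of -2.36 with a standard error of 0.19 (limma, adjusted p = 1.83e-04). Both of these probe sets carry a suffix that marks possible cross-hybridisation. The third Cadm1 probe set had a mean signal of 196.7 and was below the signal filter. Its signals were 294.6 ± 72.3 and 98.8 ± 115 (SD, n = 2), and in a fit of all probe sets its log2 change was -1.45 (limma, adjusted p = 0.649). The deleted part of the gene is not given in the labels, so a probe set outside it would check nothing. With a spread estimate that ignored signal intensity, neither probe set passed (limma, adjusted p = 0.143 and 0.275).

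The second comparison asked which transcripts differed between Tslc1-/- and Tslc1+/+ testis. Of 7975 tested probe sets, 86 passed (limma, Benjamini-Hochberg adjusted p under 0.05), 67 lower and 19 higher in Tslc1-/-, and they stood for 59 and 17 distinct genes. The probe sets called lower were mostly bright ones: the median signal was 10339 for them, 2617 for those called higher and 777.4 for all tested. Calls are easier at high signal: simulated changes of log2 size 1 were recovered in 98.2% above a signal of 5000 and 28.3% below. Among the 250 brightest tested probe sets, 25 fell and 1 rose. The median fall was 1.72-fold, and 29 of the 86 probe sets changed at least 2-fold, 19 lower and 10 higher. On all 86, both Tslc1-/- arrays lay on one side of both Tslc1+/+ arrays.

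**Figure D1:**
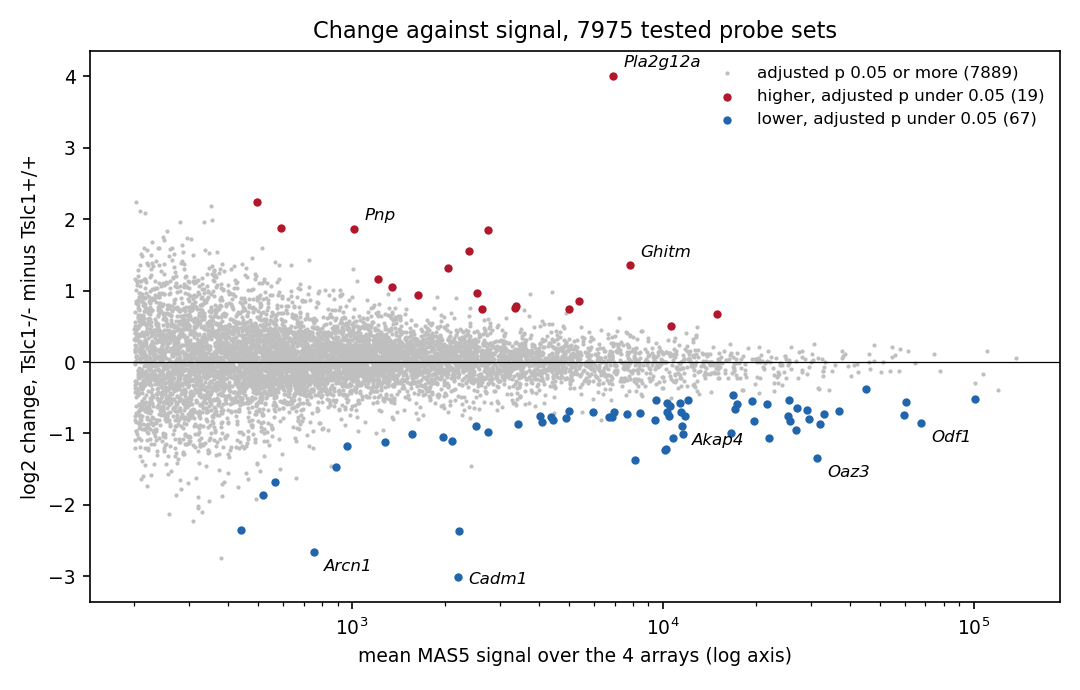
Log2 change (Tslc1-/- minus Tslc1+/+, vertical axis) against mean MAS5 signal over the 4 arrays (horizontal log axis) for the 7975 tested probe sets, 1 point each. Red points are the 19 probe sets that rose and blue points the 67 that fell at a limma adjusted p under 0.05, and the blue points lie mostly at high signal.

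The largest rise was that of Pla2g12a, a secreted phospholipase A2, from 771.3 ± 120 to 13103 ± 849 (SD, n = 2), a log2 change of 4.01 with a standard error of 0.15 (limma, adjusted p = 6.44e-07). A second Pla2g12a probe set, below the signal filter, read 302.2 and 281.4 in Tslc1+/+ and 42.5 and 43.9 in Tslc1-/-. Its log2 change was -1.87, so the probe sets of this gene moved apart. Both carry a suffix that marks possible cross-hybridisation. Pnp, which encodes purine nucleoside phosphorylase, rose from 410.1 ± 28.9 to 1629 ± 6.08 (SD, n = 2), a log2 change of 1.87 (limma, adjusted p = 0.00223). Rex1bd rose by 2.24 (limma, adjusted p = 0.0206) and Dcaf12, a substrate receptor of a ubiquitin ligase, by 1.56 (limma, adjusted p = 0.0138). A probe set annotated to the microRNA gene Mir686 rose by 1.85 (limma, adjusted p = 5.16e-04). It read polyadenylated RNA through a poly(T) primer, so it does not measure the mature microRNA.

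The largest fall after Cadm1 was on the probe set of Arcn1, which encodes the delta subunit of the COPI vesicle coat, from 1331 ± 7.50 to 178.2 ± 97.4 (SD, n = 2), a log2 change of -2.67 (limma, adjusted p = 0.00495). The other Arcn1 probe sets were below the signal filter, with log2 changes of 0.82 and -0.63. The called Arcn1 probe set carries a suffix that marks possible cross-hybridisation. Nmur1, a receptor for neuromedin peptides, fell by 2.35 (limma, adjusted p = 0.0352) and the potassium channel gene Kcnn1 fell by 1.86 (limma, adjusted p = 0.038). Dhrsx, a short-chain dehydrogenase gene, fell from 11760 ± 621 to 4509 ± 125 (SD, n = 2), a log2 change of -1.37 (limma, adjusted p = 1.35e-04). Oaz3, the ornithine decarboxylase antizyme made in haploid germ cells, fell from 44962 ± 1477 to 17735 ± 715 (SD, n = 2), a 2.53-fold decrease with a log2 change of -1.34 and a standard error of 0.08 (limma, adjusted p = 2.31e-05).

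**Figure D2:**
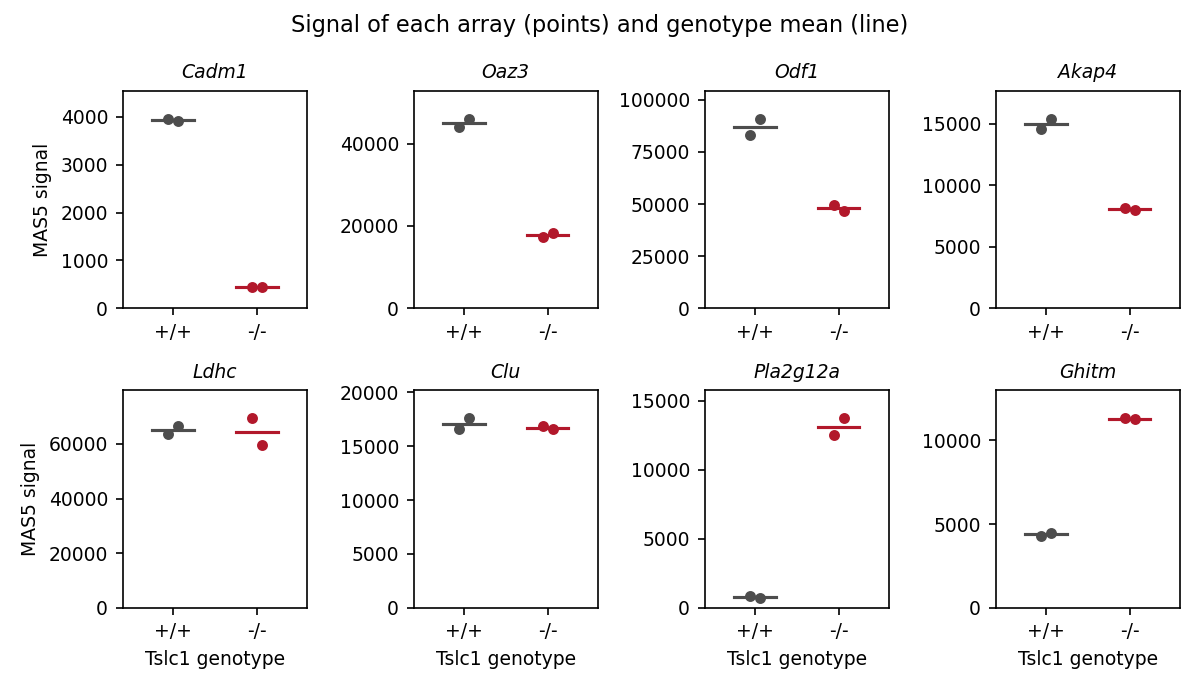
MAS5 signal of each array (points, linear axis from 0) and mean of each genotype (lines) for 8 genes, 2 arrays per genotype. Cadm1, Oaz3, Odf1 and Akap4 fell, Pla2g12a and Ghitm rose, and Ldhc and Clu, with log2 changes of -0.02 and -0.03, did not pass the test. Ghitm was chosen for this plot after its values were seen.

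Each of the calls depended on letting the spread follow signal intensity: without that trend, limma called 0 probe sets, with 638 at an unadjusted p under 0.05 against 799 with it. The count was 42 without Tslc1+/+ replicate 1, 37 without Tslc1+/+ replicate 2, 41 without Tslc1-/- replicate 1 and 43 without Tslc1-/- replicate 2, of which 36, 34, 36 and 40 were among the 86. With all 12422 probe sets tested, 58 passed, 10 higher and 48 lower, and Rex1bd (adjusted p = 0.091), Nmur1 (adjusted p = 0.113) and Kcnn1 (adjusted p = 0.152) did not. Nmur1 and Kcnn1 did not pass with any 1 of the 4 arrays left out (limma, adjusted p = 0.0849 to 0.333 and 0.112 to 0.328). Kcnn1 also did not pass over probe sets of mean signal of at least 500 (limma, adjusted p = 0.0511). Rex1bd and Nmur1 had mean signals below 500 and were not tested there. Rex1bd read 140.5 ± 16.4 in Tslc1+/+ and 850.8 ± 92.1 in Tslc1-/- (SD, n = 2). Nmur1 read 767.8 ± 92.6 in Tslc1+/+ and 111.3 ± 26.4 in Tslc1-/- (SD, n = 2). Each was thus dim in 1 genotype. With 1 array left out, Rex1bd passed only without Tslc1+/+ replicate 1 (adjusted p = 0.0529 to 0.372 without each other array), as did Dcaf12 (0.0677 to 0.194). Arcn1 did not pass without either Tslc1+/+ array (limma, adjusted p = 0.107 and 0.105), nor Pnp without either Tslc1-/- array (limma, adjusted p = 0.0714 and 0.072). Pla2g12a, Dhrsx, Oaz3 and the Mir686 probe set passed with each array left out.

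The third comparison asked which cell types and pathways of the testis moved together, over 22 gene lists fixed before the data were examined, of which 21 had the 3 tested genes that were required. Elongating spermatid transcripts were lower as a list, with a median change of -0.46 (camera, Benjamini-Hochberg adjusted p = 1.28e-14), but the list was not called with an estimated correlation (camera, adjusted p = 0.279) or by fry (adjusted p = 0.0958). Of 13 tested members, 6 fell and 7 did not pass over all genes tested, 9 fell when adjusted over the list alone, and none rose. Odf1, a protein of the sperm tail's outer dense fibres, fell from 86981 ± 5452 to 48184 ± 1955 (SD, n = 2), a log2 change of -0.85 (limma, adjusted p = 3.00e-04). Akap4, the main scaffold protein of the fibrous sheath, fell by 0.90. Prm3 fell by 0.76, while its other tested probe set was at -0.27. Gapdhs, the sperm form of a glycolytic enzyme, fell by 0.51, and a second called Gapdhs probe set was at -0.80. The transition protein gene Tnp1, which acts as histones give way to protamines, fell by 0.53. Oaz3 was the sixth member that fell.

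The other 7 elongating spermatid genes did not pass. Tnp2, the brightest of the list, had 135767 ± 1546 and 104214 ± 13383 (SD, n = 2), a log2 change of -0.39 (limma, adjusted p = 0.0654). Tnp2 passed with quantile normalization (-0.31, adjusted p = 0.00461), with equal array medians (0.0416), over probe sets with no cross-hybridisation suffix (0.028) and without Tslc1-/- replicate 1 (0.0182), and had adjusted p from 0.0569 to 0.668 under the other alternatives, the replicate block aside (limma). Smcp, a mitochondrial capsule protein of sperm, had a log2 change of -0.39 (limma, adjusted p = 0.0579) and Capza3 one of -0.46 (limma, adjusted p = 0.074). Changes were -0.13 for Prm1, 0.05 for Actl7b and 0.13 for Haspin, and the Prm2 probe set was dim, at 258.7 and 294.6.

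Round spermatid transcripts were also lower as a list, with a median change of -0.27 (camera, adjusted p = 5.56e-08), but the list was not called with an estimated correlation (camera, adjusted p = 0.43) or by fry (adjusted p = 0.0958). All 11 tested members had a negative change, of which 4 fell over all genes tested and 5 when adjusted over the list alone. Gsg1, a germ cell membrane protein gene, fell from 74629 ± 4209 to 44710 ± 420 (SD, n = 2), a log2 change of -0.74 (limma, adjusted p = 5.16e-04). Tcp11, a testis gene linked to sperm motility, fell by 0.55, the spermatid kinase Tssk2 fell by 0.54, and Theg fell by 0.87. The related kinase Tssk1 had a log2 change of -0.27 (limma, adjusted p = 0.325) and the spermatid transcription regulator Crem one of -0.08. Tcp11 did not pass without Tslc1+/+ replicate 2 (limma, adjusted p = 0.0529) or with all probe sets tested (adjusted p = 0.066).

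Of 13 tested flagellum genes, 2 fell, Odf1 and Akap4, and 11 did not pass. Adjusted over the list alone, 5 fell and 1 rose. Spa17 and Odf2, proteins of the sperm fibrous sheath and outer dense fibres, had log2 changes of -0.40 and -0.36, and the axonemal dynein gene Dnah8 one of 0.42 (limma, adjusted p = 0.0614, 0.0749 and 0.139). The median change was -0.22 (camera, adjusted p = 0.00115), with adjusted p = 0.787 with an estimated correlation, and fry gave adjusted p = 0.225. This call rested on the 3 genes shared with the elongating spermatid list, Odf1, Akap4 and Smcp. The other 10 had a median of 0.02 (camera, adjusted p = 0.567), a subset chosen after the data were seen. The flagellum list also did not pass with quantile normalization (median -0.16, adjusted p = 0.116), without the intensity trend (adjusted p = 0.113) or without Tslc1-/- replicate 2 (median -0.23, adjusted p = 0.0811).

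**Figure D3:**
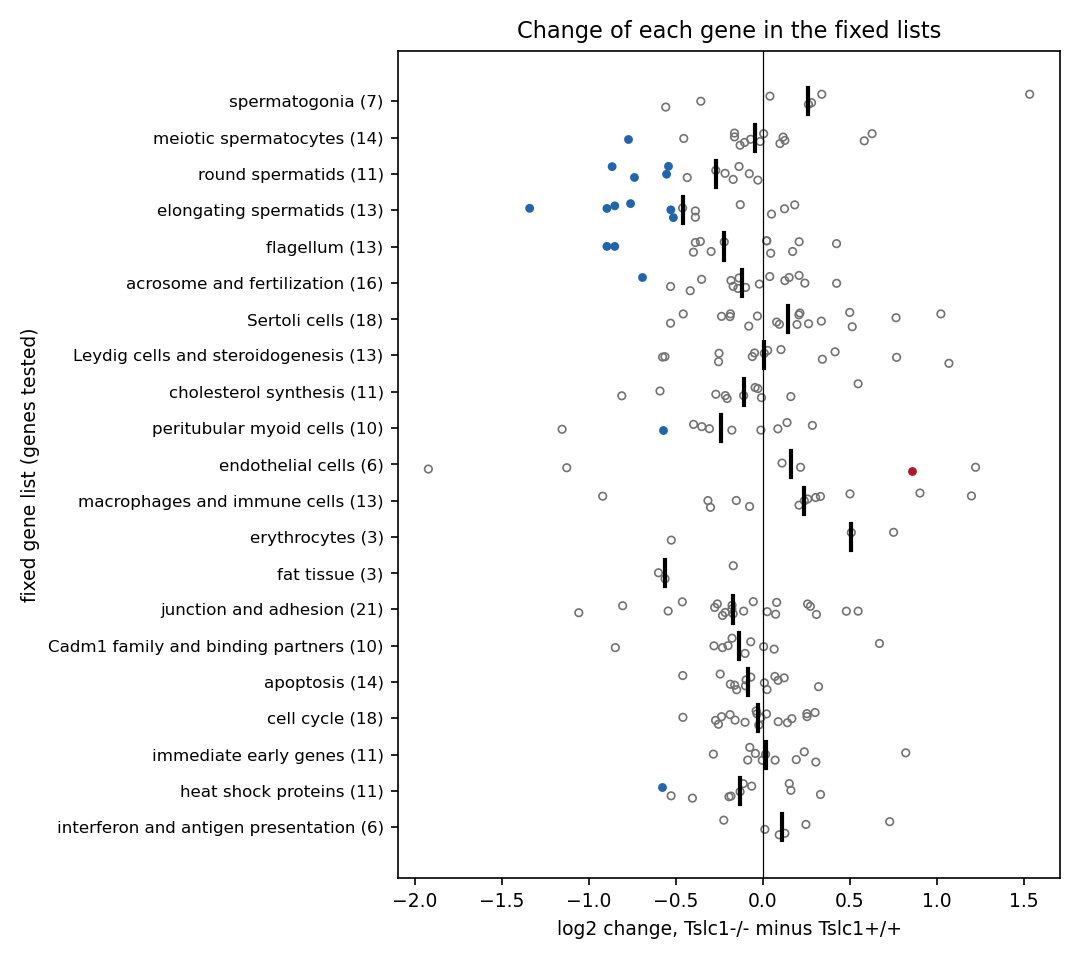
Log2 change (Tslc1-/- minus Tslc1+/+, horizontal axis) of each tested gene in the 21 fixed lists, with the number of genes in brackets. Filled blue points fell and filled red points rose at a limma adjusted p under 0.05, open points did not pass, and black bars are list medians, lowest among lists of more than 3 genes for elongating spermatids at -0.46.

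Earlier germ cell and acrosome groups were not called. Of 14 meiotic spermatocyte genes, 1 fell, the germ cell phosphoglycerate kinase Pgk2, by 0.78 (limma, adjusted p = 0.00495), and the list median was -0.04 (camera, adjusted p = 0.567). Ldhc, the testis lactate dehydrogenase and the brightest of that list, had 65042 ± 2158 and 64522 ± 6755 (SD, n = 2). None of 7 spermatogonial genes passed, with Dazl, an RNA-binding protein of germ cells, at -0.36 (limma, adjusted p = 0.244; its other tested probe set was at 0.25) and a list median of 0.26 (camera, adjusted p = 0.87). Of 16 acrosome and fertilization genes, 1 fell, the testis serine protease Prss39, by 0.69 (limma, adjusted p = 0.00956), while Spam1, the sperm hyaluronidase, had a change of -0.53 and Adam2, a subunit of fertilin, one of 0.42. Adjusted over the list alone, 2 fell and 1 rose in that list, which had a median of -0.12 (camera, adjusted p = 0.217). Pgk2 passed only when Tslc1-/- replicate 2 was the array left out (adjusted p = 0.0529 to 0.0774 without each other array), and Prss39 only without Tslc1+/+ replicate 2 (0.088 to 0.11).

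Somatic cell groups of the testis were not called either. None of 18 Sertoli cell genes passed, and their median change was 0.15 (camera, adjusted p = 0.603). Clu, a secreted chaperone abundant in Sertoli cells, had 17080 ± 710 and 16714 ± 214 (SD, n = 2), and Abca1, a cholesterol exporter, had a change of 0.77 (limma, adjusted p = 0.325), while its other tested probe set was at -0.22. None of 13 Leydig cell and steroidogenesis genes passed over all genes tested, and 1 rose and 1 fell when adjusted over the list alone. They were Hsd3b6 (log2 change 1.07) and Cyp17a1, an enzyme of androgen synthesis (-0.58, limma, adjusted p = 0.127). The median of this list was 0.01 and its mean 0.08, while camera gave the direction as down (adjusted p = 0.932). Nr5a1, a regulator of steroidogenic genes, had a change of -0.05.

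Of 10 peritubular myoid genes, 1 fell, the smooth muscle actin gene Actg2, by 0.57 (limma, adjusted p = 0.0192), and the list median was -0.24 (camera, adjusted p = 0.412). The Actg2 probe set carries a cross-hybridisation suffix. Its mean signal in Tslc1+/+ was 12337, against 2621 for Mylk, the next brightest of the list, so its fall need not come from myoid cells. Of 6 endothelial genes, 1 rose, Ly6e, by 0.86 on the log2 scale (limma, adjusted p = 0.0343), while Pecam1, an endothelial adhesion molecule, had a change of -1.92 (limma, adjusted p = 0.0694) and fell only when adjusted over the list alone. The endothelial list had a median of 0.16, a mean of -0.11 and camera adjusted p = 0.87 upward. A second Ly6e probe set had a change of -0.10, and both Ly6e probe sets carry a cross-hybridisation suffix. Of 13 macrophage and immune genes none passed, with a median of 0.24 (camera, adjusted p = 0.567) and Laptm5 at 0.90 (limma, adjusted p = 0.395). The 3 erythrocyte genes had a median of 0.51 (camera, adjusted p = 0.617), with the globin gene Hba-a1 at 0.75 (limma, adjusted p = 0.144), which in the main fit rose only when adjusted over the list alone. The 3 fat tissue genes had a median of -0.56 (camera, adjusted p = 0.412), with the leptin gene Lep at -0.60 (limma, adjusted p = 0.68). Adam7 was the only tested epididymis gene, at -0.50 (limma, adjusted p = 0.851). Actg2 did not pass with any array left out (0.0907 to 0.183), nor Ly6e without any array but Tslc1+/+ replicate 1 (0.153 to 0.25), nor either with all probe sets tested (limma, adjusted p = 0.0525 and 0.0981). Without Tslc1-/- replicate 2 the fat tissue list had a median of -1.33 and passed (camera, adjusted p = 0.0148).

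Adhesion and stress pathways were not called. None of 21 junction and adhesion genes passed, with a median of -0.17 (camera, adjusted p = 0.474) and the integrin gene Itgb1 at -0.54 (limma, adjusted p = 0.404). None of 10 genes of the Cadm1 family and its binding partners passed, with a median of -0.14 (camera, adjusted p = 0.617) and the scaffold gene Dlg1 at 0.67 (limma, adjusted p = 0.525). The 14 apoptosis genes had a median of -0.08 (camera, adjusted p = 0.87), with none passing and the survival gene Bcl2l1 at 0.32 (limma, adjusted p = 0.345) and, on a probe set below the signal filter, -0.46. The 18 cell cycle genes had a median of -0.03 (camera, adjusted p = 0.87), with none passing and the checkpoint kinase Bub1 at -0.27 and, on probe sets below the signal filter, 0.51 and -0.86. None of 11 cholesterol synthesis genes passed (median -0.11, camera adjusted p = 0.603), with Sqle at -0.27. The 11 immediate early genes had a median of 0.02 (camera, adjusted p = 0.87), with Btg2 at -0.28. The 6 interferon and antigen presentation genes had a median of 0.11 (camera, adjusted p = 0.603), with H2-K1 at 0.25. Of 11 heat shock genes, 1 fell, the spermatid chaperone Hspa1l, by 0.58 (limma, adjusted p = 0.0112), with a list median of -0.13 (camera, adjusted p = 0.177). Hspa1l did not pass with any array left out (limma, adjusted p = 0.0531 to 0.133), and without Tslc1+/+ replicate 1 the heat shock list had a median of -0.27 and passed (camera, adjusted p = 0.0486). For the meiotic, spermatogonial, Sertoli, peritubular, immune, fat tissue, adhesion, Cadm1 family, apoptosis, cell cycle, cholesterol, immediate early, interferon and heat shock lists, the counts adjusted over the list alone were the same as over all genes tested.

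Some control probe sets also differed between the genotypes. The beta-actin signal at the 3' end over that at the 5' end was 1.20 and 1.43 in Tslc1+/+ and 1.56 and 1.73 in Tslc1-/-. The same ratio for Gapdh was 1.06 and 1.12 against 0.953 and 0.925. The 18S ribosomal RNA 5' signal was 5343 ± 177 in Tslc1+/+ and 7670 ± 744 in Tslc1-/- (SD, n = 2), a ratio of 1.44, and the ratios were 1.27 for the middle and 1.17 for the 3' probe set of 18S. The bioB 5' and cre 3' spike-in controls had ratios of 1.03 and 1.06, and their signals overlapped between the genotypes.

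The fourth comparison counted large changes with no test. At least 2-fold change with no overlap between genotypes was seen for 313 probe sets, 159 higher and 154 lower. The other ways to split the 4 arrays into pairs gave 262 and 268, with limma calling 0 probe sets in each (245 and 215 at an unadjusted p under 0.05). Without overlap of any size, there were 3187 probe sets or 40.0%, where chance gives 33.3%. Leaving out 1 array, the count was 598 and 549 without Tslc1+/+ replicates 1 and 2, and 510 and 626 without Tslc1-/- replicates 1 and 2. It was 80 with 200 added to each signal, 63 over probe sets of mean signal of at least 500 and 794 with no filter.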

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

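The flagellum list without its shared genes was chosen after the data were seen, and the other alternatives before. The set of calls rested on the intensity trend. Without it, 0 probe sets passed, 0 higher and 0 lower (limma, 638 at an unadjusted p under 0.05), and Cadm1 kept its changes of -3.01 and -2.36 with adjusted p = 0.143 and 0.275; over the other alternatives run on these probe sets the adjusted p was at most 0.00986. Both carry a cross-hybridisation suffix, so the alternative without such probe sets was not run on them. In the simulation the untrended fit recovered 0% of log2 changes of 1 above a signal of 5000. Its spread was drawn from the trended fit, so this loss was built in and does not support the trend. Calls numbered 85 and 91 with pseudocounts of 1 and 200, 87 at a minimum signal of 500, 85 with quantile normalization (77 shared with the 86) and 92 with equal medians (85 shared). With no filter 58 passed, all among the 86, 10 higher and 48 lower. Leaving out 1 array gave 37 to 43 calls, 4 to 14 higher and 28 to 39 lower, with fewer arrays in the fit. The count of 313 large changes was 80 with a pseudocount of 200, 794 with no filter, 63 at a minimum signal of 500 and 510 to 626 with 1 array left out, where a lone array overlaps less easily.

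The replicate block gave 239 calls, 85 higher and 154 lower, with all 86 among them. Deviations from the genotype means correlated with r = -0.0012 between same-numbered arrays across 7975 probe sets. The replicate numbers thus marked no shared deviation, which does not show how the arrays were handled. The block ended no call of a gene list, and Tnp2, Cyp17a1 and Hba-a1 passed with it.

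With an estimated correlation or with fry, 0 lists were called; the medians stayed at -0.46 (elongating spermatids), -0.27 (round spermatids) and -0.22 (flagellum). The simulated lowered list was likewise never called with an estimated correlation. The elongating and round spermatid lists passed in the 13 other alternatives run on each, with medians from -0.52 to -0.31 and -0.43 to -0.22. The flagellum list had -0.16 with quantile normalization and -0.22 with no trend, both not passing, and -0.28 to -0.16 with 1 array left out, not passing without Tslc1-/- replicate 2. Without the shared genes it turned to 0.022 (camera, adjusted p = 0.567). The full list was nearly evenly split, with 7 negative and 6 positive changes, and the 3 genes taken out all had negative ones.

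Apart from the called flagellum list without its shared genes, the values that turned sign were these, none of them a call and the cause not tested. Most lay near 0, but the fat tissue list (-0.56), Lep (-0.60) and Adam7 (-0.50) did not. The Leydig list (0.0091) was -0.0024 with a pseudocount of 200, -0.054 at a minimum signal of 500, -0.011 with equal medians and -0.046 to 0.047 with 1 array left out. The immediate early list (0.016) was -0.0031 with no filter, -0.023 at a minimum signal of 500, -0.0036 with equal medians, -0.0031 with the mean of a gene's probe sets and -0.062 to 0.17 with 1 array left out. With no filter the apoptosis list was 0.017. With quantile normalization the meiotic list was 0.033, Ldhc 0.14 and Clu 0.090. With 1 array left out, ranges were -0.10 to 0.43 for the endothelial list, -0.27 to 0.053 for heat shock, -0.18 to 0.0047 for acrosome, -1.33 to 0.13 for fat tissue and -0.18 to 0.060 for junctions. They were -0.12 to 0.092 for Ldhc, -0.073 to 0.012 for Clu, -1.33 to 0.13 for Lep, -0.13 to 0.041 for Nr5a1 and -1.09 to 0.086 for Adam7. Low signal limits precision for dim probe sets: below 500 the median SD was 0.43 and 2 of 2721 probe sets passed. It does not account for Ldhc, Clu and Nr5a1, which were bright and turned sign too.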

Other observations

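The tests in this part were chosen after the patterns were seen. The prediction for the control ratios, that for an equal drop and that for carried-over DNA were also written after the values they concern, as were the lists of glycolysis and of protein kinase A with its anchors.

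Of 20 tested glycolysis genes, 10 had a negative and 10 a positive change, and 5 fell and none rose: Pkm, pyruvate kinase, from 13204 ± 230 to 7785 ± 250 (SD, n = 2) with a log2 change of -0.76, Pgk2 at -0.78, the testis aldolase Aldoart2 at -0.69, Aldoa at -0.58 and Gapdhs at -0.51 (limma, adjusted p from 0.00258 to 0.0168). The other 15 did not pass, among them Hk1 at 0.54 (limma, adjusted p = 0.239), Pfkl at 0.42, Pfkp at 0.34, Pfkm at 0.26, Hk2 at -0.53, Ldhc at -0.02, Ldha at 0.11 and Pgam2 at -0.22. The list's median was 0.04 and its mean -0.12. The Pkm, Aldoa and Gapdhs probe sets given here carry a suffix that marks possible cross-hybridisation, so their falls need not be separate. Pgk2, Gapdhs and Ldhc are also in the fixed germ cell lists, and the list was drawn up because some of its members had been called, so a set test on it would restate that choice.

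Of 11 tested genes of protein kinase A and the proteins that anchor it, 4 fell and none rose: the regulatory subunit Prkar2a from 14295 ± 1358 to 6074 ± 1026 (SD, n = 2) with a log2 change of -1.23, and the anchors Akap1 at -0.95, Akap4 at -0.90 and Akap12 at -0.70 (limma, adjusted p from 5.16e-04 to 0.00716). A second called Akap1 probe set was at -0.82. The other 7 did not pass: the anchors Akap2 at 0.87 and Akap8 at 0.69 (limma, adjusted p = 0.621 and 0.588), Akap9 at -0.00, the regulatory subunits Prkar1b at -0.52 and Prkar1a at 0.03, and the catalytic subunits Prkaca at -0.15 and Prkacb at 0.02. The median was -0.15. This list too was drawn up after the calls were seen, so a set test would restate that choice, and Akap4 is also in the elongating spermatid and flagellum lists.

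The lower spermatid lists were set against technical explanations. Random lists were matched on signal in bins of 100 genes. Medians as low were found in 0.03% of 10000 such lists for elongating spermatids, 0.48% for round spermatids and 1.42% for the flagellum list, whose median rests on 3 shared genes. This argues against distortion shared by probe sets of like signal as the whole cause. Such bins match the very brightest members only loosely. Quantile normalization moved the medians from -0.46, -0.27 and -0.22 to -0.31, -0.22 and -0.16, and the flagellum list did not pass. Part of the fall may thus be distortion. A single equal drop of the measured signals is argued against for the 11 members brighter than 5000 on these arrays. They ranged from -1.34 for Oaz3 (standard error 0.08) to 0.05 for Actl7b (standard error 0.09). Their spread exceeded the errors (Cochran's Q with limma standard errors, chi-square p = 4.74e-44). Those errors may be technical and folds of different probe sets need not be on 1 scale. Fewer elongating spermatids with unaltered content is therefore not excluded. RNA quality stays open: the beta-actin 3' over 5' ratio was higher in Tslc1-/- and the Gapdh one lower, at 0.865 of Tslc1+/+, so the controls go opposite ways. Fewer late spermatids and lower transcript levels within them both stay open; spermatid counts or RNA of sorted spermatids, not analysed here, would be needed to tell them apart.

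Some called genes lay near one another on the chromosomes of assembly GRCm38.p6. Within 10 Mb there were 48 pairs among 73 called genes other than Cadm1, where random draws matched on signal had a median of 33 and a central range of 21 to 50, and 394 of 10000 draws had as many or more. Within 10 Mb of Cadm1, 3 of 69 tested genes were called (Arcn1, H2ax and Ift46) against 70 of 5912 elsewhere (Fisher's exact test, p = 0.0516), so DNA carried over from another strain, a candidate explanation, is neither shown nor excluded. By chromosome, the share of called genes passed on none of the 20 tested (Fisher's exact test, Benjamini-Hochberg adjusted p of at least 0.125). On chromosomes 8, 9 and 14 the adjusted p was 0.562, 0.649 and 0.622 (Fisher's exact test). The bounds first written for called genes lying near one another gave firmer readings. For carried-over DNA, the bounds for and against it were both met. Only 394 of 10000 draws had as many pairs, and 4.35% of genes near Cadm1 were called against 1.18% elsewhere, which would have counted for it. The 48 pairs also lay inside the central range, which would have counted against it and was the reading first given. For pairs among the genes that rose, p = 0.178 (permutation test by random draws) would have counted for chance neighbours among spermatid genes. Of 5 other probe sets of neighbouring called genes on chromosomes 8, 9 and 14, the only chromosomes used for this count, 3 moved the same way. This would have counted against sequence variants under single probe sets, while 12 of 24 over all called genes (50%) would have counted for them. All 3 readings first given were changed to undecided after the results were seen, since a genome-wide count forbids no single segment, 16 risen genes and 5 probe sets are few, and the genes that fell showed no clear excess either (27 pairs, permutation p = 0.127).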
